A study of Homo sapiens with 2 samples.

How the data were processed

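Total RNA of Huh7 cells, a human hepatocellular carcinoma line, was extracted with Trizol, labelled with biotin and hybridised to 1 array per group, per the labels' protocols. One array is the control, whose label carries the abbreviation NTC, and the other the CD47 knockdown. Both come from cultures given a lentiviral construct or its control, per the labels. The construct's sequence and the number of cultures pooled are not given in the sources used here. The deposited values are signal intensities on a linear scale, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes. MAS5 summarises the probes of a probe set after subtracting mismatch signal and scales each array. The version and settings are not given in the sources used here. The trimmed mean of all values, with 2% left off at each end, was 499.9 on both arrays, so the values are already scaled to one another. MAS5 gives positive values to transcripts that are absent, so a ratio of low values carries mostly noise. Detection calls were not used here.

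The table holds 54675 probe sets, of which 62 are array controls. The platform annotation gave 1 gene for 41097 probe sets and several genes for 1801, a few array controls included. It gave none for 11721 of the probe sets that are not controls. Symbols were updated through the Entrez gene identifier to the RefSeq annotation of GRCh38.p14 for 41043 probe sets, and the annotation's own symbol was kept for the others. Only probe sets with 1 gene were named, which left 19775 genes. Each gene took the values of its probe set with the highest mean log2 signal over both arrays. Of 3 genes to be reported whatever their values, 1 is not analysed here. No genome coordinates are given, since the annotation names no build for the probe sets.

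A floor was set at the geometric mean of the medians of both arrays (76.6). Values at or under it were set to it before log2 was taken, so a fold against it is a lower bound. A gene was counted as different when the brighter array was above the floor and the ratio reached 2-fold. The ratio is knockdown over control throughout. Arrays limit the precision by their number, here 1 per group. No test between groups was possible without replicates, so none was made. The only error estimated is the disagreement between the 2 brightest probe sets of a gene, as the SD of their difference in log2 ratio divided by the square root of 2. It covers probe sets and not cultures or hybridisations.

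Before the data were examined, 45 gene lists were fixed. Each list's median log2 ratio over members above the floor on at least 1 array was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. A list stood apart below percentile 2.5 or above percentile 97.5, and lists with fewer than 5 such members had no median. The lists hold 1197 different genes, of which 1085 had a probe set of their own. Some genes belong to several lists. The genes to be named were fixed by a rule at the same time: CD47, CTSS and the gene not analysed here whatever their values, then the 10 highest and 10 lowest ratios among genes above the floor on both arrays, past 2-fold and with all probe sets above the floor on the same side. The rule added the 3 largest bounds in each direction and up to 4 members per list with the largest ratios. Genes without an approved name and sex-linked genes that identify a donor's sex were left out of it.

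The other settings, all but one chosen before the data were examined, were median, quantile and loess scaling of the arrays, no floor, a floor at the 75th percentile of the probe sets (418.4), a floor from genes not expected in liver (78.2), the median of a gene's probe sets, and leaving out probe sets named _x_at or _s_at, whose probes can match several transcripts or genes. Folds of 1.5 and 3, probe sets all of the same sign and 10 bins of signal were also used. Leaving out members that another list holds was added after the data were seen.

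Array controls were compared first. The ratio of 3' to 5' signal of GAPDH was 1.04 on the control and 1.05 on the knockdown array, and that of ACTB 11.4 and 9.19. The ACTB ratios were far above those of GAPDH, so signal from the 5' end of ACTB was low on both arrays. Whether other transcripts were affected likewise was not tested. The median log2 ratio was -0.05 for 18 hybridisation spike-in probe sets and 0.04 for 24 labelling spike-in probe sets. The calculation was tested on a simulated copy of the control array with the probe set noise (SD 0.33). The changed genes were drawn from those well above the floor on the control array. Of 50 changed 3-fold in each direction, 96% of the higher and 98% of the lower were recovered, and all of those changed 6-fold. Recovery among dimmer genes was not tested. Among 19575 unchanged genes, those under the floor included, 10 were called higher and 12 lower. The same SD was used at all signals, although the probe sets of the dimmest genes had an SD of 0.41. Both SDs come from probe sets above the floor on both arrays, and noise under the floor was not estimated. The counts of unchanged genes called therefore say little of genes at the floor on either array. Of 60 lists of 20 genes picked at random, 5% stood apart with no shift, 95% with a log2 shift of 0.3 and 100% with 0.6. Genes in these lists do not vary together, as those of the fixed lists may. The simulated noise holds no difference between cultures, so the simulation says nothing of how many genes 2 control cultures would differ by. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots matplotlib 3.10.9.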

Results

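Gene expression was measured on 2 arrays of Huh7, a cell line established from a human hepatocellular carcinoma. One array held RNA of control cells. The other held RNA of cells in which CD47 had been repressed with a lentiviral construct, with 1 array per group. CD47 is a cell surface protein that binds SIRPA on phagocytes, a contact that restrains engulfment, and thrombospondin-1. The comparison addresses which transcripts differ between liver cancer cells given a construct against CD47 and those given its control. Effects of the construct other than the loss of CD47 cannot be told apart from that loss here. With 1 array per group there is no replicate check: no test was made, no p-value is given, and each difference describes these 2 arrays. Signal intensities had the same trimmed mean on both arrays (499.9), with medians of 78.4 in the control and 74.9 in the knockdown. Of 19775 genes with a probe set of their own, 12294 lay above the floor of 76.6 on the control array and 12053 on the knockdown array. The floor is the geometric mean of both medians, and a gene at or under it on one array has a fold that is only a lower bound, written "at least".

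The targeted transcript was lower in the knockdown array. The brightest CD47 probe set (213857_s_at) had a signal of 2113 in the control and 149.7 in the knockdown, which is 14.1-fold lower (log2 ratio -3.82). Probe set 211075_s_at was 13.8-fold lower and 226016_at, with a signal of 416.5 in the control, was 3.85-fold lower. Probe set 213055_at lay close to the floor on both arrays (89.4 and 93.0) and showed no such difference. Probe set 227259_at was above the floor in the control alone, and the 2 others lay under the floor on both arrays, where no fold is given. Of 12922 genes above the floor on at least 1 array, CD47 had the log2 ratio ranked 4 from the lowest. The brightest probe set carries the suffix _s_at, which marks a probe set that matches several transcripts. The gene's log2 ratio was -1.95 as the median of its probe sets.

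CTSS, which encodes the lysosomal cysteine protease cathepsin S, was named before the data were examined because other work on liver cancer cells had linked it to CD47. Its brightest probe set (232617_at) had signals of 368.2 and 99.9 and was 3.69-fold lower in the knockdown (log2 ratio -1.88). Both of its other probe sets were also lower. CTSS ranked 136 from the lowest of the 12922 genes. It was the only member of the list of cathepsins and their cystatin inhibitors that was at least 2-fold different: the other 14 of the 15 members above the floor were within 2-fold, and the list's median log2 ratio of -0.16 lay among those of random lists (percentile 11.1). Cathepsin E, which that list does not hold, is among the lowest genes described further on. CTSS has no signal above the floor of 418.4 that the 75th percentile gives.

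**Figure D1:**
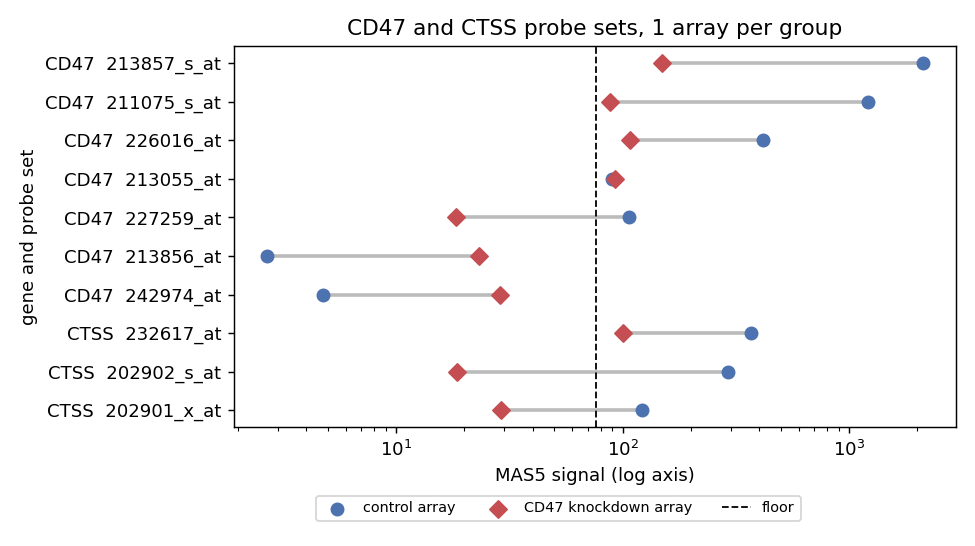
Signal of each CD47 and CTSS probe set (rows) on the control array (circles) and the CD47 knockdown array (diamonds), on a log axis, with the floor of 76.6 as a dashed line. The brightest CD47 probe set went from 2113 to 149.7 and the brightest CTSS probe set from 368.2 to 99.9.

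Across the arrays, 310 genes were at least 2-fold higher and 766 at least 2-fold lower in the knockdown, so 71.2% of the genes past 2-fold were lower. They were 8.33% of the genes above the floor. In 53 of the higher genes the control array was at the floor, and in 157 of the lower genes the knockdown array was. At 4-fold or more, 28 genes were higher and 111 lower. Across genes above the floor on both arrays, the log2 signals had a Pearson r of 0.96 and the median log2 ratio was 0.00071, so the middle gene had the same level on both arrays. Genes are not independent replicates. The technical error that these arrays can show is the disagreement of a gene's probe sets: the SD of a log2 ratio between the 2 brightest probe sets of a gene was 0.33 over 5427 genes, 0.41 in the dimmest 1809 of them and 0.24 in the brightest 1809. Of 487 genes past 2-fold with at least 2 probe sets above the floor, 404 (83.0%) had all of them on the same side, although each was picked by the ratio of one of these probe sets. Among genes within 2-fold with at least 2 such probe sets, the share was 52.9%. The error between cultures was not measured. The counts depend on the floor: without one they were 2301 higher and 2850 lower, and with the floor of 418.4 they were 136 and 297.

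The genes with the lowest ratios included several that liver cells secrete. CFI, the complement factor that cleaves C3b and C4b, had signals of 5007 and 330.2 and was 15.2-fold lower in the knockdown. C4BPB, a chain of the complement inhibitor C4b-binding protein, was 12.8-fold lower, and HP, which encodes the haemoglobin-binding plasma protein haptoglobin, 8.64-fold lower. Cathepsin E (CTSE), an aspartic protease, was 13.6-fold lower. Enzymes and transporters of liver metabolism were also among them: the alcohol dehydrogenase ADH1B (9.09-fold lower), the fatty acid transport protein and acyl-CoA synthetase SLC27A2 (9.30-fold lower) and the mitochondrial adenylate kinase AK4 (9.34-fold lower). The others of the 10 were the microvillar cadherin CDHR2 (9.57-fold lower), the ubiquitin ligase TRIM31 (9.50-fold lower) and the kinase NRK (9.30-fold lower). Other genes were at the floor in the knockdown. SERPINA7, the thyroxine-binding globulin of plasma, was at least 15.9-fold lower, the glycosyltransferase B3GNT7 at least 14.3-fold lower, and SLC2A2, the glucose transporter GLUT2 of hepatocytes, at least 8.82-fold lower. The log2 ratio of B3GNT7 was -3.84 by its brightest probe set and -3.07 as the median of its probe sets.

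The genes with the highest ratios were led by NTS, which encodes the secreted peptide neurotensin, with signals of 232.0 and 2832, 12.2-fold higher in the knockdown. The matrix proteoglycan versican (VCAN) was 8.40-fold higher, and its 5 probe sets were all higher. The matrix glycoprotein EFEMP1 was 6.32-fold higher. MT1M, a metal-binding metallothionein, was 6.45-fold higher. The trefoil peptides TFF1 and TFF3, secreted by mucosal epithelia, were 5.66-fold and 5.11-fold higher, and SLC26A3, a chloride and bicarbonate exchanger of the intestine, 5.76-fold higher. LAMP5 was 7.13-fold higher, HEPACAM2 5.62-fold and RGS2, a regulator of G protein signalling, 5.43-fold. HAL, the histidine-degrading histidine ammonia-lyase, was at least 11.5-fold higher, GP2 at least 6.25-fold and the Notch target HEY2 at least 5.05-fold, all with the control at the floor. Without probe sets that carry the suffix _x_at or _s_at, HEY2 was under 2-fold (log2 ratio 0.76). As the median of its probe sets, HAL had a log2 ratio of 2.62 in place of 3.52. Probe sets of CTSE, C4BPB, CDHR2, TRIM31, SLC27A2, ADH1B, HP, VCAN and EFEMP1 used here carry these suffixes.

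**Figure D2:**
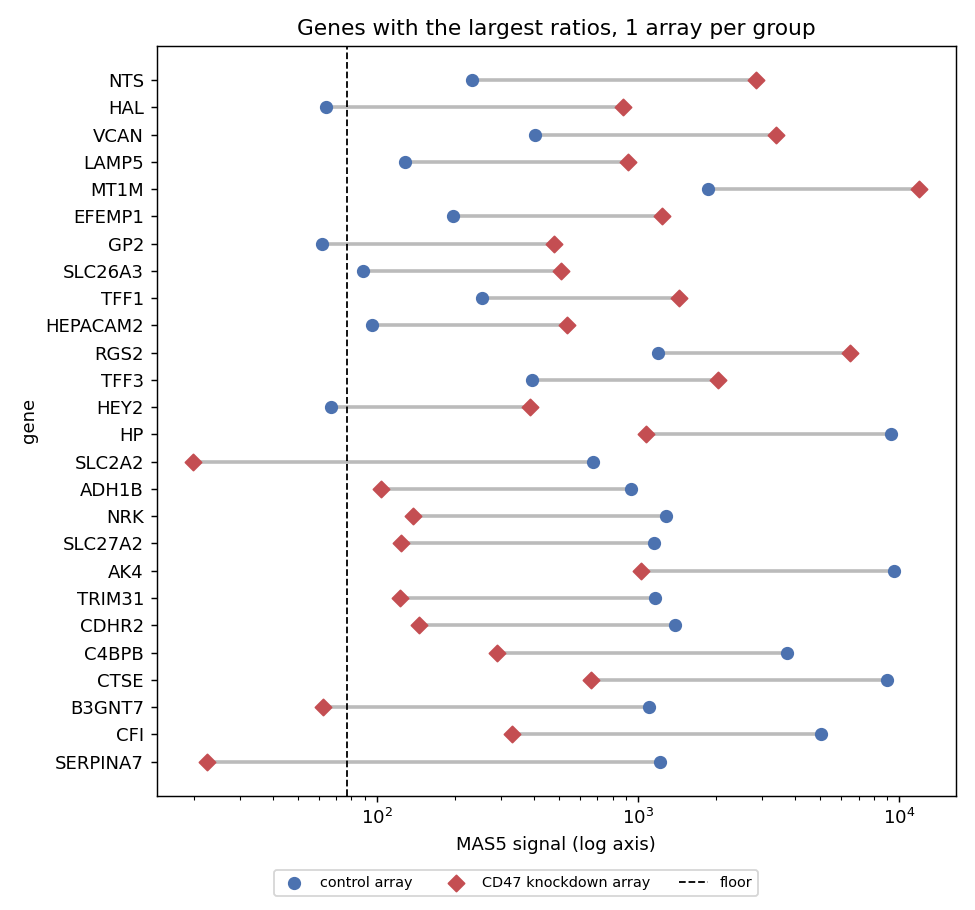
Signal of the genes with the largest ratios (rows, ordered by log2 ratio) on the control array (circles) and the CD47 knockdown array (diamonds), on a log axis, with the floor of 76.6 as a dashed line. NTS went from 232.0 to 2832 and CFI from 5007 to 330.2.

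Gene lists fixed before the data were examined were compared with 10000 random lists of the same size and signal. Of the 44 lists with a median, 15 lay below and 4 above the middle 95% of the random lists, and 25 lay within it. About 5% would lie outside by construction if the members of a list were unrelated genes. Genes of a list can vary together between any 2 cultures, so more than 5% may lie outside without an effect of CD47. A list outside this range stands apart in these 2 arrays, which is no test of the conditions. Quartiles and medians are over the members above the floor on at least 1 array.

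**Figure D3:**
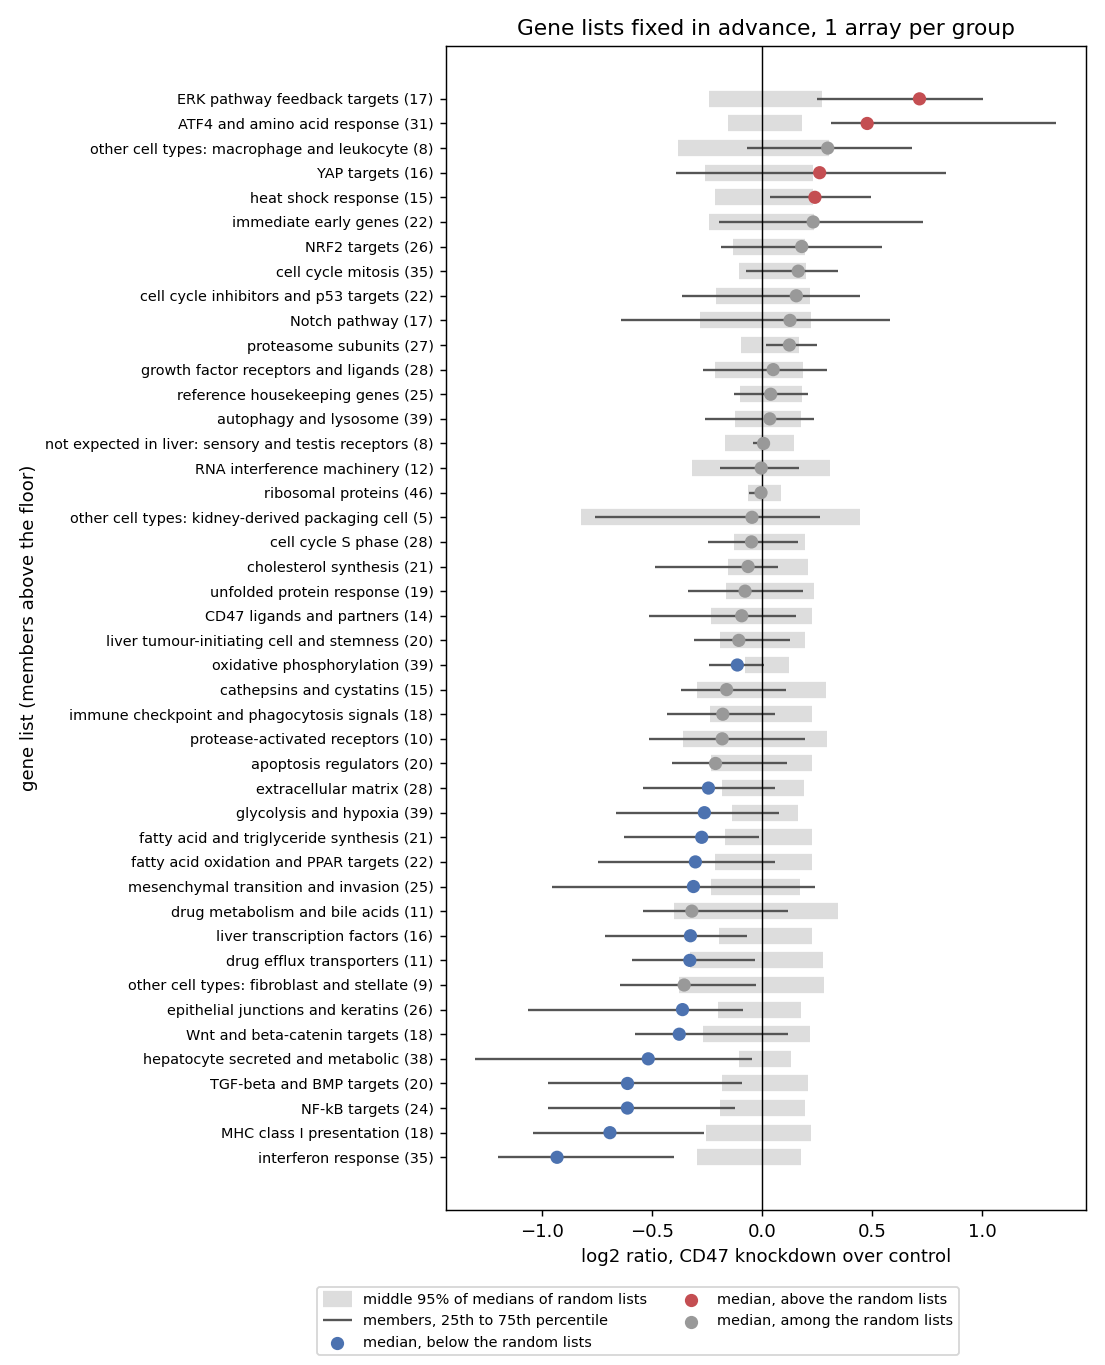
Median log2 ratio (points) of each gene list with the 25th to 75th percentile of its members (dark lines) and the middle 95% of the medians of random lists (grey bars), with the number of members above the floor in brackets. The interferon response list has the lowest median (-0.93) and the list of ERK pathway feedback targets the highest (0.71).

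Genes of interferon signalling and antigen presentation were lower in the knockdown array. The interferon response list had a median log2 ratio of -0.93 over 35 members, below all random lists (percentile 0). Of these 35, 32 were lower and 16 at least 2-fold lower, none at least 2-fold higher. The chemokine CXCL10 went from 4997 to 851.5 (5.87-fold lower), the antiviral oligoadenylate synthetase OAS3 was 4.51-fold lower, IFIT1 2.96-fold lower and the immunoproteasome subunit PSMB9 at least 3.11-fold lower. With the floor of 418.4 the interferon list's median was -0.52 and still stood apart. The list of MHC class I presentation had a median of -0.69 over 18 members (percentile 0), of which 7 were at least 2-fold lower, among them PSMB9, HLA-B (log2 ratio -1.26) and HLA-F (-1.21). ERAP1, the peptide-trimming aminopeptidase of the same list, had a log2 ratio of -1.26 by its brightest probe set and -0.25 as the median of its probe sets. HLA-F was at -0.87 by the same median. HLA genes are near-identical in sequence and share probes. Without probe sets of the suffixes _x_at and _s_at, the list's median was -0.29 and no longer stood apart (percentile 7.53).

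Targets of NF-kB, the transcription factor of inflammatory signalling, had a median of -0.61 over 24 members (percentile 0), with 6 at least 2-fold lower and none at least 2-fold higher. They included the adhesion molecule VCAM1 (4.55-fold lower), the chemokine CXCL6 (3.53-fold lower), TNFAIP2 (log2 ratio -1.46) and TNFAIP3 (-1.25), an inhibitor of the same pathway. The NF-kB median was -0.31 (percentile 0.91) without probe sets of the suffixes _x_at and _s_at. The list of immune checkpoint and phagocytosis signals, the pathways in which CD47 acts, lay among the random lists with a median of -0.18 over 18 members (percentile 6.60). Its members with the largest ratios went both ways: MICB, a ligand of the NKG2D receptor (1.58), and the bridging protein MFGE8 (1.23) were higher, and the complement regulator CD55 (-1.49) and PROS1 (-1.22) lower. Known ligands and partners of CD47 had a median of -0.09 over 14 members (percentile 18.6). In that list the thrombospondins THBS1 (3.51-fold higher) and THBS4 (2.83-fold higher) were past 2-fold, and LRP1 (log2 ratio -0.88) and ITGA5 (-0.72) were within 2-fold. THBS1 had a log2 ratio of 0.68 without probe sets of the suffixes _x_at and _s_at. Apoptosis regulators had a median of -0.21 over 20 members (percentile 3.46), with the death ligand TNFSF10 (4.42-fold lower) and BIK (at least 2.19-fold lower) past 2-fold.

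Many genes of differentiated hepatocyte function were lower. The list of secreted and metabolic hepatocyte genes had a median of -0.52 over 38 members (percentile 0), 30 of them lower and 13 at least 2-fold lower, with none at least 2-fold higher. Beside HP, the urea cycle enzymes CPS1 (6.77-fold lower) and OTC (6.51-fold lower) and the fatty acid binding protein FABP1 (3.01-fold lower) had the lowest ratios. The other 25 members were within 2-fold, and several bright ones were nearly level. Among these were the apolipoproteins APOA1 (log2 ratio -0.14), APOA2 (0.04) and APOE (0.003) and the fibrinogen chains FGA (0.07), FGB (0.08) and FGG (-0.03). APOA1, APOA2, FGB and FGG had control signals above 20000, where the scanner may saturate and a ratio may be understated. This was not tested. Liver transcription factors had a median of -0.33 over 16 members (percentile 0.24), but FOXA1 (-1.18) alone was at least 2-fold lower. TBX3 (-0.83), PROX1 (-0.73) and CEBPA (-0.72) were within 2-fold, and TBX3 was at -0.06 as the median of its probe sets. Enzymes of drug metabolism and bile acids had a median of -0.32 over 11 members, which lay among the random lists (percentile 8.27), with CYP3A5 (-1.35) and CYP27A1 (-1.18) lower and CYP1A1 (1.13) higher. With the floor of 418.4 this list had a median of -0.73 and stood apart (percentile 0.47). Drug efflux transporters had a median of -0.33 over 11 members (percentile 2.49), and both ABCC2 (3.06-fold lower) and ABCB1 (2.85-fold lower) were past 2-fold. That list stood apart in 1 of the 8 other settings and under none of the 3 other scalings, where its percentiles were 2.68, 2.74 and 2.61. With 10 bins of signal its percentile was 3.52.

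Lists of lipid and energy metabolism also lay low. Fatty acid oxidation and PPAR targets had a median of -0.30 over 22 members (percentile 0.47), with 5 at least 2-fold lower, among them ACADL (at least 5.35-fold lower), ECI2 (3.12-fold lower) and FABP1. ACADL had a log2 ratio of -2.42 by its brightest probe set and -1.56 as the median of its probe sets. ANGPTL4, of the same list, was at least 2.29-fold higher. Genes of fatty acid and triglyceride synthesis had a median of -0.28 over 21 members (percentile 0.24), with AGPAT2 (3.12-fold lower), the transcription factor MLXIPL (at least 2.51-fold lower) and PNPLA3 (log2 ratio -1.02) past 2-fold. Glycolysis and hypoxia genes had a median of -0.26 over 39 members (percentile 0.05). Only 3 of these were past 2-fold in that direction, SLC2A2, NDRG1 (4.47-fold lower) and PFKFB3 (log2 ratio -1.96), and 35 were within 2-fold. Oxidative phosphorylation had a median of -0.11 over 39 members (percentile 0.31), and none of them was 2-fold different. Cholesterol synthesis had a median of -0.06 over 21 members (percentile 14.8), all within 2-fold.

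Genes of the ATF4 and amino acid response, which cells induce when amino acids are short or the integrated stress response is active, were higher. The median was 0.48 over 31 members (percentile 100), of which 12 were at least 2-fold higher and none at least 2-fold lower. The secreted stress cytokine GDF15 was 4.97-fold higher, the mitochondrial folate enzyme MTHFD2 4.47-fold, the glycoprotein hormone STC2 4.29-fold and the cystine transporter SLC7A11 3.88-fold. GDF15 had a log2 ratio of 2.31 by its brightest probe set and 1.39 as the median of its probe sets. The unfolded protein response list includes chaperones of the endoplasmic reticulum. It lay among the random lists with a median of -0.08 over 19 members (percentile 11.6). NRF2 targets had a median of 0.18 over 26 members (percentile 96.3): SLC7A11, NQO1 (1.40) and UGDH (1.24) were higher and ABCC2 lower. The NRF2 list stood apart without a floor (median 0.28, percentile 99.75) and without probe sets of the suffixes _x_at and _s_at (0.32, percentile 99.5). The heat shock list had a median of 0.24 over 15 members (percentile 97.9), in which the HSP90 co-chaperone FKBP4 (1.26) alone was past 2-fold, and BAG3 (-0.89) and DNAJB1 (-0.76) were lower. FKBP4 was 0.94 as the median of its probe sets. The heat shock list no longer stood apart in 3 of the 8 other settings (percentiles 96.9, 97.3 and 95.5), nor with random lists drawn from 10 bins of signal (96.2).

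Feedback targets of the ERK pathway, which this growth factor cascade induces and many of which restrain it, had the highest median, 0.71 over 17 members (percentile 100). Of these, 5 were at least 2-fold higher and none at least 2-fold lower. The phosphatase DUSP5 went from 1822 to 8139 (4.47-fold higher), SPRED1 had a log2 ratio of 1.44, the receptor EPHA2 1.13 and DUSP4 1.06. YAP targets had a median of 0.26 over 16 members (percentile 98.6), with CCN1 (2.76-fold higher), CCN2 (2.67-fold higher), AMOTL2 (log2 ratio 1.15) and PTPN14 (1.03) past 2-fold. PTPN14 was 0.61 as the median of its probe sets, and without a floor the YAP list had a median of 0.21 (percentile 91.7). Immediate early genes lay just inside the random lists, with a median of 0.23 over 22 members (percentile 97.4). In 4 of the 8 other settings this list stood apart on the higher side: with the floor of 418.4 (percentile 99.2), with the floor from genes not expected in liver (97.51), with the median of each gene's probe sets (median 0.38, percentile 99.97) and without probe sets of the suffixes _x_at and _s_at (0.53, percentile 99.95). EGR1 (2.95-fold higher), CCN1 and CCN2 were higher and KLF2 (3.31-fold lower) was lower. KLF2 had a log2 ratio of -0.84 without probe sets of the suffixes _x_at and _s_at. Growth factor receptors and ligands had a median of 0.05 over 28 members (percentile 72.4), with PDGFRA (5.06-fold higher), FGF19 (3.12-fold higher) and IGFBP2 (log2 ratio 1.24) higher. PDGFRA had a log2 ratio of 1.17 as the median of its probe sets and 0.73 with the floor of 418.4.

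Lists of cell shape and matrix lay low with members on both sides. Epithelial junction and keratin genes had a median of -0.36 over 26 members (percentile 0.01), with 7 at least 2-fold lower and none at least 2-fold higher. KRT19 was 3.94-fold lower, MARVELD3 had a log2 ratio of -1.46, claudin-3 (CLDN3) -1.42, and EPCAM was 2.55-fold lower. Genes of mesenchymal transition and invasion had a median of -0.31 over 25 members (percentile 0.48), with 6 at least 2-fold lower and 2 at least 2-fold higher. The matrix protein SPARC was 6.23-fold lower, the intermediate filament vimentin (VIM) 2.91-fold lower and LOXL2 had a log2 ratio of -1.40, whereas the receptor TGFBR2 was at 1.11. TGFBR2 was 0.72 as the median of its probe sets, and SPARC had a log2 ratio of -2.64 by its brightest probe set and -1.98 without probe sets of the suffixes _x_at and _s_at. Extracellular matrix genes had a median of -0.25 over 28 members (percentile 0.64). Most were within 2-fold (25 of 28). COL4A6 (-1.59) was lower, and VCAN and BGN (1.05) were higher. Without members that other lists also hold, which was tried after the data were seen, the matrix list no longer stood apart (percentile 3.01).

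Targets of TGF-beta and BMP had a median of -0.61 over 20 members (percentile 0), with 5 at least 2-fold lower and 3 at least 2-fold higher. The inhibin chains INHBB and INHBA were at least 6.98-fold and at least 3.04-fold lower, and the iron hormone hepcidin (HAMP) had a log2 ratio of -2.18, whereas CCN2 was higher. Wnt and beta-catenin targets had a median of -0.38 over 18 members (percentile 0.34), with the secreted Wnt inhibitor WIF1 (-1.38) alone past 2-fold and AXIN2 at -0.65 and ZNRF3 at -0.60. This list no longer stood apart without a floor (median -0.17, percentile 12.6) or with the median of each gene's probe sets (-0.10, percentile 22.5). Notch pathway genes had a median of 0.13 over 17 members (percentile 88.5), and the related targets HEY2 and HEY1 went apart: HEY2 was higher and HEY1 was 3.24-fold lower.

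The list of liver tumour-initiating cell and stemness genes lay among the random lists, with a median of -0.11 over 20 members (percentile 11.5). KRT19, EPCAM and ANPEP (-1.16) were at least 2-fold lower and DLK1 (1.42) higher, and the other 16 were within 2-fold. Genes of S phase had a median of -0.05 over 28 members (percentile 15.8) and none was 2-fold different. Mitosis genes had a median of 0.16 over 35 members (percentile 94.0), with the kinesin CENPE (1.10) alone past 2-fold. Cell cycle inhibitors and p53 targets had a median of 0.15 over 22 members (percentile 92.2), with GDF15 higher and CDKN1A (-1.14) lower. Autophagy and lysosome genes had a median of 0.03 over 39 members (percentile 53.9). Protease-activated receptors and their proteases had a median of -0.18 over 10 members (percentile 14.4), and of -0.47 with the floor of 418.4, where they stood apart (percentile 0.78).

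Lists that served as controls lay among the random lists. The median was -0.01 for 46 ribosomal proteins (percentile 28.4), 0.04 for 25 reference housekeeping genes (percentile 53.7), 0.12 for 27 proteasome subunits (percentile 91.7) and -0.01 for 12 genes of the RNA interference machinery (percentile 45.1), in which AGO4 was at -1.64. Of 57 sensory receptor, lens, testis and hair keratin genes on the array, which a liver cell is not expected to use, 8 were above the floor, with a median of 0.01 (percentile 61.9). Markers of other cell types were in part above the floor. Macrophage and leukocyte markers had 8 of 20 members above the floor, with a median of 0.30 (percentile 97.3), and 5 of the 8 were higher. LYZ, which encodes lysozyme, had signals of 11505 and 18660 (log2 ratio 0.70), CORO1A and CD3D were higher from a control at the floor (at least 1.63-fold and at least 1.60-fold), and CD14 was at least 2.68-fold lower. The list stood apart with the median of each gene's probe sets (percentile 97.7). Fibroblast and stellate cell markers had 9 of 15 above the floor, with a median of -0.36 (percentile 3.45), in which PDGFRA was higher and TAGLN (-1.20), COL1A2 (-0.90) and COL1A1 (-0.65) lower. COL1A2 had signals of 2191 and 1178. TAGLN was at 0.33 without probe sets of the suffixes _x_at and _s_at. Markers of the kidney-derived cells used to package lentivirus had 5 of 10 above the floor, with a median of -0.05 (percentile 55.2). Of 13 endothelial markers, 1 was above the floor (PECAM1, log2 ratio -0.08), and no median was taken.

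The rule for naming genes and the families of the closing section give 130 genes beside CD47 that were at least 2-fold different, some of which the text does not name. With the floor at 418.4, 16 of them came under 2-fold and 27 had no signal above it. Those under 2-fold included SLC26A3, HEPACAM2, GP2, SLC2A2, SPRED1, HLA-B, HLA-F, ABCC2, INHBB, WIF1, CCN1, PDGFRA, FOXA1 and TAGLN. Folds of genes that lay near the floor on one array became smaller in the same setting. The log2 ratio was then -1.17 for ADH1B, -1.46 for SLC27A2, -1.48 for TRIM31, -1.61 for NRK, -1.73 for CDHR2, -1.69 for CPS1, -1.44 for OTC and -1.45 for SPARC. It was 2.76 for NTS, 1.77 for TFF1, 1.57 for EFEMP1, 1.13 for LAMP5 and 1.03 for FGF19. The bounds became -1.54 for SERPINA7, -1.39 for B3GNT7 and 1.07 for HAL.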

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

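Probe sets that name no gene or several genes were not used in the comparisons, yet some of them differed between the arrays. Of 5546 such probe sets above the floor, 92 were at least 2-fold higher in the knockdown and 254 at least 2-fold lower. The larger number lay on the lower side, as for the named genes, and no gene is assigned to them.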

How the results depend on the processing

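Of the 19 gene lists that stood apart, 14 did so in the same direction in all 8 other settings of scaling, floor and probe sets, and 18 under all 3 other scalings, the exception being drug efflux transporters. With members of other lists left out, tried after the data were seen, 16 did, and the extracellular matrix, YAP and drug efflux lists did not. Across all lists and the families added after the data were seen, 426 medians moved by less than their bootstrap SD and 28 by more. None of those that stood apart changed sign, but some others did, among them the macrophage and leukocyte list (-0.05 without a floor, against 0.30). The counts of genes moved most with the floor and the fold. Without a floor 2301 genes were higher and 2850 lower (55.3% lower, against 71.2%), since dim probe sets then count in full. With the floor at the 75th percentile there were 136 and 297, at 1.5-fold 1234 and 1877, and at 3-fold 65 and 243. The share of lower genes was 65.8% under quantile and 68.5% under loess scaling. The scalings moved the median gene by at most 0.03. The log2 ratio of CD47 was -2.34 with the floor at the 75th percentile, which raises the knockdown value, and -1.95 both as the median of its probe sets and without probe sets named _x_at or _s_at, which leaves a dimmer probe set. TAGLN was at 0.33 without those probe sets, against -1.20, and HSPA4, within 2-fold in both settings, at -0.71 against 0.61. The cause was not tested. For the other genes of the naming rule and families, 1466 values moved by less than the probe set SD of their signal range and 101 by more. Of the 130 genes past 2-fold that the naming rule and the added families give, some of them not named in the text, 49 had a value past 2-fold in every one of the 8 settings. The suffix setting left 42 of them without a value, and 9 came under 2-fold.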

Other observations

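The gene families and all tests in this part were chosen after the data were seen. Some families hold genes already seen at the extremes, among them CFI, C4BPB, ADH1B and MT1M. The percentiles of such families are therefore no independent support. Metallothioneins, small proteins that bind zinc and copper, were higher in the knockdown array in all 7 members above the floor, each at least 2-fold (median log2 ratio 1.67, percentile 100 of random lists). They ranged from MT2A at 1.39 to MT1M at 2.69, with MT1G at 2.07 and MT1F at 1.71. Their sequences are near-identical, so the probe sets do not measure 7 separate genes, and the median was between 1.63 and 1.67 in the 7 other settings that gave one. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include known ATF4 targets, had a median of 0.53 over 17 members (percentile 100), 14 of them higher. LARS1 (1.04), FARSB (0.81), EPRS1 (0.70) and GARS1 (0.61) had the largest ratios, though LARS1 was 0.38 as the median of its probe sets. Serine and one-carbon enzymes had a median of -0.10 over 12 members (percentile 15.2), in which MTHFD2 (2.16) stood alone past 2-fold. They stood apart on the lower side with the floor at the 75th percentile (median -0.25, percentile 2.10) and without probe sets named _x_at or _s_at (-0.32, percentile 1.82).

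Complement genes, which liver cells secrete into plasma, had a median of -0.97 over 23 members (percentile 0), with 11 at least 2-fold lower. The lowest were CFI (-3.92), C4BPB (-3.68), C8B (-2.85) and C6 (at most -2.44, the knockdown being at the floor). MASP1, a protease of the lectin pathway, was higher (1.42). Alcohol and aldehyde dehydrogenases had a median of -0.61 over 18 members (percentile 0.01), with ADH1B (-3.18), ADH1A (-2.19), ALDH8A1 (-2.07) and ADH6 (-2.06) lowest among those above the floor on both arrays, and ADH1C at most -1.88 with the knockdown at the floor. The ADH1 genes share most of their sequence. Both of these medians stood apart in all 8 other settings. Coagulation factors and inhibitors had a median of -0.37 over 21 members (percentile 0.04), with SERPIND1 (-1.45) and F11 (at most -1.32) lowest and 7 members above 0. Apolipoproteins had a median of -0.56 over 15 members (percentile 0.01), with APOL2 (-2.09) and APOC3 (-1.42) lowest, but did not stand apart with the floor at the 75th percentile (percentile 6.29) or without probe sets named _x_at or _s_at (3.47). APOL2 was -0.93 as the median of its probe sets, and APOA1 (-0.14), APOA2 (0.04) and APOE (0.003) were nearly level. The signals of APOA1 and APOA2 are among those bright enough that the scanner may saturate. In the urea cycle CPS1 and OTC were lower and ARG2 (1.88) higher, with a median of -0.37 over 9 members that stood apart in the main setting (percentile 1.89) and in 4 of the 8 other settings. It did not under quantile (3.16) or loess scaling (2.70), with the floor at the 75th percentile (2.68) or without probe sets named _x_at or _s_at (median -0.22, percentile 13.2). ARG2 was 0.82 in the last of these. With the floor at the 75th percentile C8B was at -0.98, ADH1B at -1.17 and ALDH8A1 at -1.17.

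The lower interferon and antigen presentation genes were set against 2 technical explanations. Noise of dim probe sets is argued against for the 7 interferon response members with a mean signal above 418.4. Their median log2 ratio was -1.07, below the 2.5th percentile of random lists of their size and signal (-0.39). The dimmer members and the list of MHC class I presentation were not put to this test. With the floor itself at 418.4, the list's median was nearer 0 (-0.52, against -0.93). Lentiviral vectors can set off innate sensing, and a difference in that between the 2 constructs may lower these genes as well as a loss of CD47 may. In the list, 91.4% of 35 members were lower, which either would give, and with 1 array per construct they cannot be told apart.

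The lower hepatocyte genes beside higher ATF4 targets were treated likewise. A smaller share of Huh7 cells in the knockdown sample would lower all hepatocyte genes by about the same factor, on top of the spread that genes show between these arrays. The SD of the log2 ratio was 1.02 over the 21 list members with a control signal under 20000 (range -3.11 to 0.73). Brighter members were left out because the scanner may saturate there. That SD lay at percentile 99.7 among random lists of the same size and signal (their median SD 0.53). This argues against a smaller share as the whole cause. A different state of the cultures at harvest, such as density or spent medium, may raise ATF4 targets (median 0.48) and lower liver genes. With 1 array per group it cannot be told apart from an effect of the knockdown.

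A clonal difference in chromosome copies between both cell populations could shift neighbouring genes together. Over 11403 genes in the order of the GRCh38.p14 annotation, the 40 neighbouring genes with the largest median (PQBP1 to ZMYM3) were at -0.35, with 33 of them lower. In 25 of 100 shuffled gene orders the largest window was as large or larger, and the highest was 0.46. The size of the observed window lay between the median (0.33) and the highest of the largest windows in the shuffled orders. It therefore decides nothing about a gained or lost segment. A segment with a smaller shift or fewer genes also cannot be told apart from the spread of single genes here.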
